A study of Macaca mulatta with 8 samples.

How the data were processed

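Total RNA from GFP+ and GFP- fractions of CD34+ bone marrow cells of 4 rhesus macaques was hybridised to Affymetrix whole-transcript arrays, 1 array per fraction and animal. Per the labels' protocols, the cells were enriched with an antibody against CD34 on magnetic beads and sorted on a flow cytometer for the GFP encoded by the vector. The deposited table holds 1 log2 signal per probeset and array, made by the authors with Affymetrix Expression Console per the submitters' processing notes. The version, the summarisation and the normalization are not given in the sources used here. The log2 scale was read from the values, which ran from 1.63 to 13.66 with array medians of 5.47 to 5.55. The close medians show arrays on a common scale, but whether and how the authors adjusted them to each other stays unknown. Scanner files were not used here, so background and detection could not be recomputed, and a low signal has no detection call.

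The values were used as deposited, with no further normalization, filter or pseudocount. The table has 40489 probesets, and all were tested. Control probesets were looked for by identifiers that start with AFFX, and 0 were found. Control probesets with other identifiers would not have been recognised and may be among those tested. Probesets were named from the array's annotation, which gave 1 gene symbol for 16020 probesets, several for 490 and none for 23979. Probesets with several symbols were left unnamed. Of 15045 Entrez identifiers among the singly named probesets 14947 were found in the RefSeq gene table of the rhesus macaque assembly T2T-MMU8v2.0, and 14947 of these had the same symbol there. The build of the array's design is not given in the sources used here, and no coordinates are reported. A group of 4434 probesets shared all 8 values with at least 1 other probeset, in 1511 sets, so counts of probesets can count a measurement more than once. Where a gene had several probesets, the gene lists used the one with the highest mean signal, and differing probesets of a named gene are reported beside it.

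Arrays were grouped by the sorted fraction and paired by the animal named in the sample titles, because both fractions were sorted from CD34+ cells of the same animal, per the labels and the series design. The pairing was checked in the data. The deviations of the GFP+ and GFP- array of an animal from their group means correlated with r between 0.471 and 0.701 across probesets, and with arrays of other animals with at most 0.193. Differences between the fractions were tested with limma version 3.58.1 (lmFit and eBayes) in R version 4.3.3, with the fraction and the animal as fixed effects. The Benjamini-Hochberg adjustment was made over all probesets at a threshold of 0.05. The same fit gave the 95% confidence intervals, and the number that lay wholly within 2-fold was counted. Differences between animals were tested with the limma F test of the animal terms in the same fit. The correlation of arrays was tested with an exact permutation test over the 24 pairings of GFP+ with GFP- arrays.

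Before the data were examined, 29 gene lists were fixed, for stem cells, the cell types of the marrow, cell cycle, stress, interferon, metabolism, restriction of retroviruses and insertion sites of vectors. They hold 833 gene symbols, of which 575 were measured. Each list with at least 5 measured genes was tested two-sided with limma camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists. Camera with a correlation estimated per list and the limma rotation test fry were alternatives. Fry tests whether the genes of a list move 1 way on balance and does not compare them with other genes. The levels of lists were also compared between animals by the number of genes that passed the F test.

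The genes named in the text followed a rule fixed together with the lists. It took up to 12 genes in each direction with an adjusted p under 0.05 and the same sign in 4 of 4 animals. Where fewer passed, it was filled up with the smallest unadjusted p among genes with the same sign in 4 of 4 animals, an absolute log2 difference of at least 0.3 and a mean signal at or above the median of all probesets. All 24 places were filled that way. It added CD34 and PTPRC, up to 2 genes in each direction per list, and the 10 genes with the largest F statistics between animals. PF4V1, GP1BA, PF4, GP9, HOXA9, IFIT2, ISG15, TRIM22, BLK and VPREB1 were named after their values were seen. So were MS4A2, TYMS, CENPF, EPX, PRG2 and FCRLA between animals, and the platelet transcripts CAVIN2, NRGN, TAGLN2 and THBS1.

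The paired fit and the list test were tested on simulated data, in which 200 of 40489 probesets were changed by known amounts with the spread of the real arrays. Of those changed by 2 on the log2 scale 90.9% were recovered, of those changed by 1 43.3% and of those changed by 0.5 1.49%, with 5 false calls. In a simulation with independent genes, a list shifted by 0.3 was called and 0 other lists were. The alternatives left out the pairing, each animal in turn, or dim probesets, and used quantile normalization, median centring, another variance model, array weights, unmoderated statistics, a random animal effect or other list tests. Detrending the differences on the signal level and counting identical probesets once were chosen after the data were seen. Other splits of the 8 arrays were fitted in the same way.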

Results

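RNA was measured on Affymetrix arrays in CD34+ cells, the stem and progenitor cells of the blood system, taken from the bone marrow of 4 rhesus macaques. Each animal had earlier received its own CD34+ cells carrying a lentiviral vector that encodes green fluorescent protein (GFP), a marker of cells that express the vector. The marrow CD34+ cells of each animal were sorted by flow cytometry into a GFP+ and a GFP- fraction, so that 4 GFP+ arrays were paired by animal with 4 GFP- arrays. Animal RQ2617 was sampled 9 years after transplantation, RQ6897 after 4 years, RQ7387 after 3.5 years and RQ7280 after 3 years. The 8 arrays gave log2 signals for 40489 probesets, of which 16020 carried exactly 1 gene symbol, for 15534 genes. The median signal of an array lay between 5.47 and 5.55. The precision is limited by the number of arrays.

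The GFP+ and GFP- fractions were compared to find transcripts that differ between marrow cells that express the vector and marrow cells of the same animal that do not. Of 40489 probesets, 7 passed the paired limma test at an adjusted p of 0.05, 6 of them higher and 1 lower in GFP+ cells, and 0 of the 7 carried a gene symbol. Probeset 13813332 had a signal of 12.55 ± 0.55 in GFP+ cells and 7.49 ± 1.01 in GFP- cells (log2, mean ± SD, n = 4), a 33.4-fold difference that was higher in 4 of 4 animals (log2 difference 5.06, 95% confidence interval 4.46 to 5.66, limma adjusted p = 0.00137). Probesets 13813454 and 13813466 held the same 8 values as 13813332. Probesets 13813384 and 13813390 were each 17.8-fold higher (log2 differences 4.15 and 4.15, limma adjusted p = 0.00137 and 0.00999), and 13813346 was 5.71-fold higher (2.51, adjusted p = 0.00181), all in 4 of 4 animals.

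The 6 probesets that were higher in GFP+ cells had 4 distinct sets of values and lay within 68 consecutive probesets of the table, 0 of which carried a gene symbol. The same holds for all 11120 probesets that follow the last named one, among which these 68 lie. In the GFP- fraction the signal of 13813332 was highest in RQ7280, at 8.87, and between 6.71 and 7.64 in the other animals. On the linear scale the GFP- signal of 13813332, which holds an unknown share of background, was between 1.63% and 5.56% of the GFP+ signal of the same animal. Without RQ2617 and its pair of arrays 2 probesets passed, and without the pairing by animal 4 passed. The smallest log2 difference of the 6 was 2.61 without RQ2617 and 2.51 without the pairing, against 2.51 in the main fit. With unmoderated paired statistics 0 probesets passed.

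**Figure D1:**
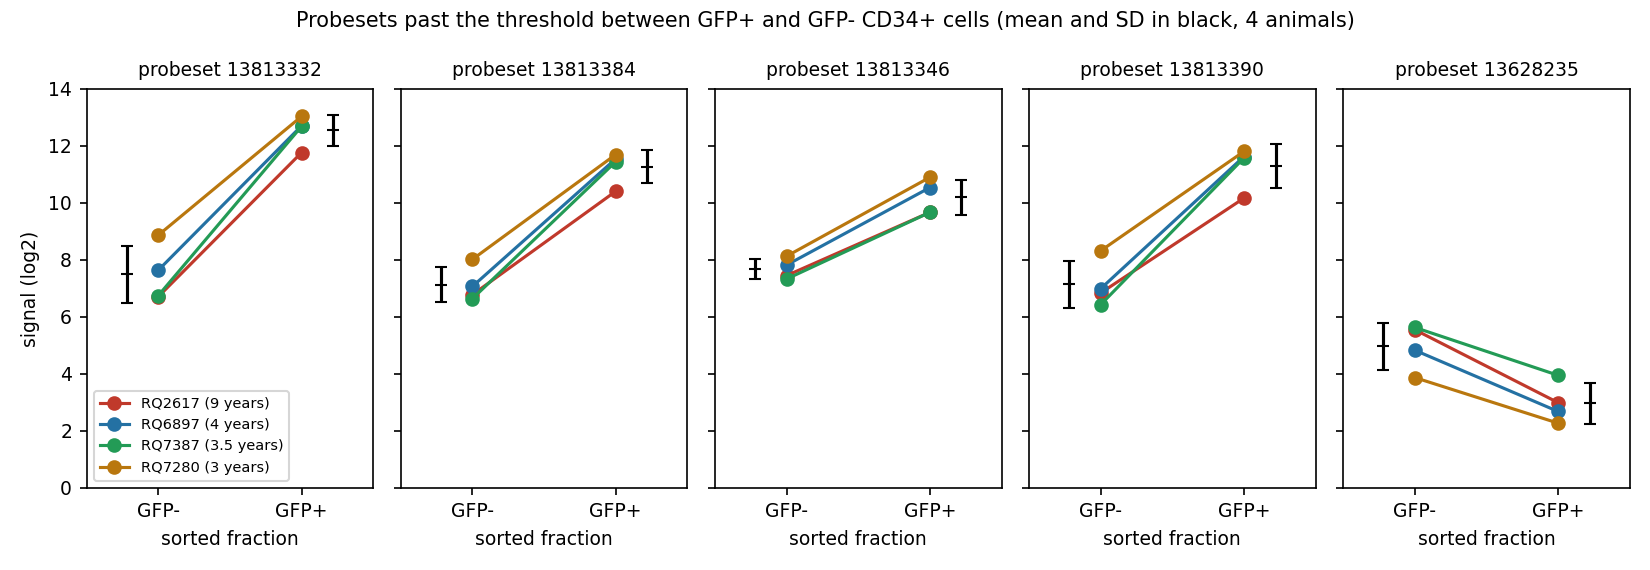
Log2 signal (vertical axis) of the 5 distinct value profiles among the probesets that passed the limma test, in the GFP- and GFP+ fraction of each animal (horizontal axis), with 1 line per animal and the mean and SD of the 4 animals in black. In each of the 4 probesets on the left the GFP+ value lies above the GFP- value by at least 2.22 in every animal, and in probeset 13628235 it lies below it in 4 of 4 animals.

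Probeset 13628235 had a lower signal in GFP+ cells, at 2.97 ± 0.72 against 4.97 ± 0.82 (log2, mean ± SD, n = 4; limma adjusted p = 0.0394; lower in 4 of 4 animals). Its GFP+ signals lay between 2.27 and 3.95, at or below the lower quartile of their array, and are not shown to be above background, so no fold is given. Its call was lost after quantile normalization (limma adjusted p = 0.129) and when any 1 animal was left out (limma adjusted p between 0.0866 and 0.291). The log2 difference itself was -2.04 after quantile normalization and -2.13 to -1.81 with 1 animal left out, against -2.00 in the main fit. After quantile normalization 6 probesets passed and all 6 were higher in GFP+ cells.

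Among the named genes PPBP had the smallest p, but 0 of 16020 probesets with 1 gene symbol passed the limma test. PPBP, a chemokine stored in platelet granules, had a signal of 10.86 ± 0.79 in GFP+ and 9.61 ± 0.58 in GFP- cells (log2, mean ± SD, n = 4; probeset 13751874), 2.39-fold higher and higher in 4 of 4 animals, with the smallest adjusted p of all named genes (limma adjusted p = 0.542). Differences above 2-fold were seen in 2 further named genes. ROCK1, a kinase that controls the actin skeleton, differed by 1.27 (log2), although its brighter probeset differed by 0.01, and PF4V1, a platelet factor gene, differed by 1.05. At an unadjusted p under 0.05 there were 512 named probesets, 250 higher and 262 lower in GFP+ cells. That is fewer than chance alone would give at this threshold, so the main fit may be strict for named probesets. When only the named probesets were tested, 835 had an unadjusted p under 0.05, 0 of them passed and the limma adjusted p of PPBP was 0.135. The separate fit also estimated the variance shared by probesets anew, so more than the number of tests changed.

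The other named genes with the smallest unadjusted p did not pass the test either, with limma adjusted p between 0.870 and 0.886. On the higher side these were RBPMS2, with a log2 difference of 0.97, RGS18, a regulator of G protein signalling in platelets, with 0.81, the store-operated calcium channel gene ORAI2 with 0.61 and the granule protein gene AZU1 with 0.51. They also included FAM216A (0.53) and the uncharacterised genes LOC707085 (0.89), LOC693354 (0.63) and LOC719770 (0.56). LOC713514 (0.69) and the ribosomal protein gene RPS12 (0.57) had other probesets with 0.09 and 0.17. On the lower side RAB30 differed by -0.58, the mitochondrial chaperone gene GRPEL1 by -0.56, PINK1, a kinase of mitochondrial quality control, by -0.56, and the microRNA genes MIR616 and MIR142 by -0.68 and -0.56. ARID5A, TBKBP1, ELL3, CD2BP2, SEPTIN1 and SHCBP1 differed by between -0.52 and -0.42, and LOC705771 by -0.56 in 1 probeset and 0.07 in another. CD34, the surface marker used to enrich the cells, was 0.40 higher in GFP+ cells in 3 of 4 animals (limma adjusted p = 0.886), and PTPRC, the common leukocyte antigen CD45, differed by -0.08.

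The 95% confidence interval of the difference, without adjustment over genes, lay wholly within 2-fold for 39002 of 40489 probesets (96.3%), and for 15927 of the 16020 with 1 gene symbol (99.4%). The median distance from the estimate to the end of its interval was 0.33 (log2). Differences had the same sign in 4 of 4 animals for 12.99% of the named probesets, and 12.5% would do so by chance. In simulated data with the spread of the real arrays, 200 probesets were changed. Of those changed by 1 on the log2 scale 43.3% were recovered, and of those changed by 0.5 1.49%. The adjustment is stricter where fewer probesets pass, and 7 passed in the real data. The simulated shares are thus likely to overstate how many changes of these sizes the real test would find.

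Taken as groups, megakaryocyte and platelet genes and stem cell genes were higher in GFP+ cells. The megakaryocyte list had a median log2 difference of 0.19, with 15 of 20 measured genes higher and its mean higher in 4 of 4 animals (limma camera adjusted p = 2.07e-06 with a preset correlation of 0.01). The call was lost at adjusted p = 0.683 with an estimated correlation. In this list 0 genes passed when adjusted over all genes and 2 passed when adjusted over the list alone. These were PPBP (limma adjusted p = 0.00375) and CLEC1B, the platelet receptor CLEC-2 (log2 difference 0.69, limma adjusted p = 0.0179). The mean signal of CLEC1B, 5.03, lay below the median of all probesets, 5.51. The platelet genes GP1BA and PF4 differed by 0.53 and 0.68 without passing. The integrin gene ITGA2B, the platelet receptor subunit gene GP9 and the growth factor gene PDGFA were at -0.10, 0.02 and -0.15.

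The list of stem cell and primitive progenitor markers had a median log2 difference of 0.12, with 21 of 25 genes higher and its mean higher in 4 of 4 animals (limma camera adjusted p = 6.15e-05). The call was lost at adjusted p = 0.683 with an estimated correlation, and 0 genes passed adjusted over all genes or adjusted over the list alone. Its largest differences were those of MECOM (0.42), CD34 (0.40), the transcription factor gene GATA2 (0.35) and the homeobox genes HOXA9 (0.34) and HOXA5 (0.34). The other probeset of MECOM, a transcription factor gene of stem cells, differed by 0.13. Both MECOM probesets, at mean signals of 4.86 and 3.915, lay below the median of all probesets, 5.51. PROM1, which encodes the stem cell marker CD133, and MSI2 were at -0.14 and -0.08. These and the megakaryocyte list were called in each fit that left out 1 animal, with adjusted p of up to 0.0308 and 0.00395. The median of the stem cell list was 0.19 without RQ2617 and 0.21 without RQ7387. Without the pairing by animal 2 lists passed, and these were the 2.

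**Figure D2:**
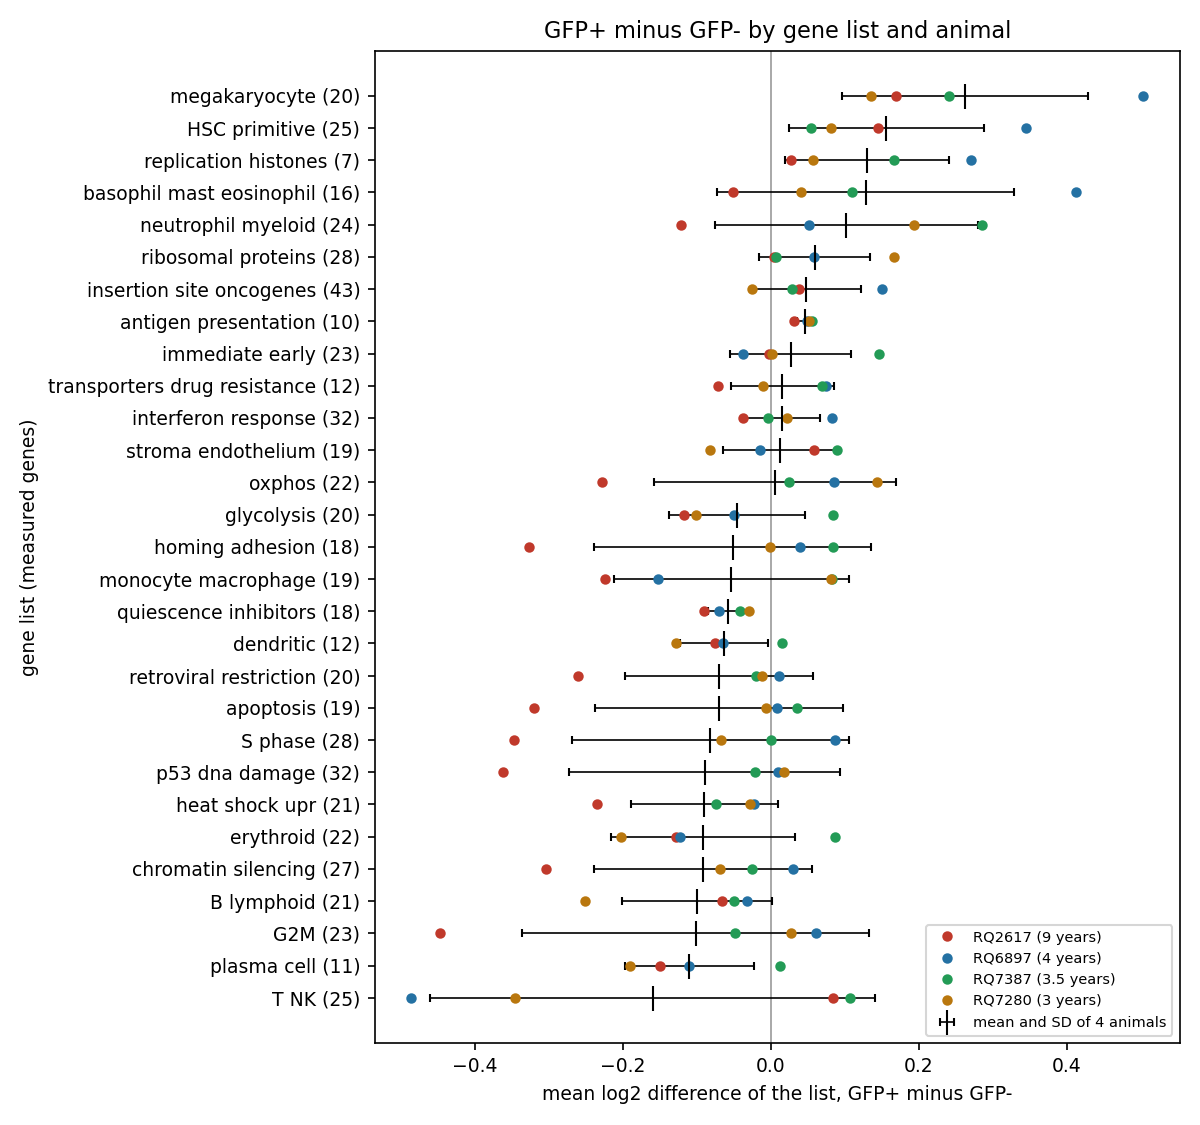
Mean log2 difference between GFP+ and GFP- cells (horizontal axis) of the measured genes of each of 29 gene lists (vertical axis, number of genes in brackets), with 1 coloured point per animal and the mean and SD of the 4 animals in black. The megakaryocyte and stem cell lists lie above 0 in 4 of 4 animals, and the T and natural killer cell list ranges from -0.49 in RQ6897 to 0.11 in RQ7387.

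Lists of 2 granulocyte groups and of replication histones were also called higher in GFP+ cells. Basophil, mast cell and eosinophil genes had a median log2 difference of 0.13, with 13 of 16 genes higher (camera adjusted p = 0.0156), among them the IgE receptor subunit gene MS4A2 (0.49) and GATA2, which is also in the stem cell list. Neutrophil and myeloid granule genes had a median of 0.11, with 17 of 24 genes higher (camera adjusted p = 0.0156). The granule protease family genes AZU1 (0.51) and CTSG (0.59) were higher there, while CXCR2, a chemokine receptor of mature neutrophils, was at -0.40 and OLFM4 at -0.24. Replication histone genes had a median of 0.17, with 5 of 7 genes higher (camera adjusted p = 0.0313), led by H2BC8 (0.37) and H1-5 (0.25), while H2BC9 was at -0.23. All 3 calls were lost at adjusted p = 0.683 with an estimated correlation, and 0 genes of these lists passed adjusted over all genes or adjusted over the list alone. The basophil list had a mean of 0.41 in RQ6897 and -0.05 in RQ2617. Without RQ6897 its call was lost and its median fell to 0.05 (adjusted p = 0.464), and without RQ2617 the median was 0.20. The neutrophil list had a mean of -0.12 in RQ2617. Its call was lost without RQ7387, with a median of 0.03 (adjusted p = 0.186), and without RQ7280 (0.141), and its median was 0.17 without RQ6897. The histone call was lost without RQ6897 or RQ7387 (camera adjusted p = 0.215 and 0.0774), although its median was 0.183 and 0.177 there, against 0.175 in the main fit.

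Lymphoid lists were called lower in GFP+ cells. T and natural killer cell genes had a median log2 difference of -0.09, with 20 of 25 genes lower (camera adjusted p = 0.0156), led by the T cell receptor complex gene CD3G (-0.83) and TRAT1 (-0.67), while the chemokine gene CCL5 was at 0.27. B-lineage genes had a median of -0.09, with 18 of 21 genes lower and the mean lower in 4 of 4 animals (camera adjusted p = 0.0315), led by the interleukin 7 receptor gene IL7R (-0.31) and FCRLA (-0.26). Both calls were lost at adjusted p = 0.683 with an estimated correlation, and 0 genes passed adjusted over all genes or adjusted over the list alone. The T and natural killer cell list was lower in RQ6897 (-0.49) and RQ7280 (-0.35) and higher in RQ2617 (0.08) and RQ7387 (0.11), and its call was lost without RQ6897, with a median of -0.00667 (adjusted p = 0.542), or RQ7280 (0.348). Without RQ2617 its median was -0.16. The B-lineage call was lost without RQ7387 (adjusted p = 0.0774), without RQ7280, with a median of -0.05 (0.393), after quantile normalization (0.0624), after detrending (0.0997) and with only probesets at or above the median (0.121). Without RQ6897 its median was -0.14. In RQ6897, where the megakaryocyte, basophil and stem cell lists differed most between the fractions (means of 0.50, 0.41 and 0.34), CD34 itself was 0.95 higher in GFP+ cells.

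The remaining 22 lists did not pass the camera test, and 9 of them passed in at least 1 other setting. Proto-oncogenes and growth regulators known from vector insertion site studies had a median log2 difference of 0.03, with 26 of 43 genes higher (camera adjusted p = 0.0713). Among them MECOM, at a low signal, was at 0.42, HOXA9 at 0.34 and MYCN at 0.32. This list passed in 6 other settings, among them quantile normalization (median 0.06, adjusted p = 0.0173) and the fit without RQ7280 (0.05, 0.0456), and was at -0.02 without RQ6897 (adjusted p = 0.542). Genes of G2 and mitosis had a median of -0.11 (adjusted p = 0.0604), with a mean of -0.45 in RQ2617 and between -0.05 and 0.06 in the other animals, and S phase genes had a median of -0.09 (adjusted p = 0.0732), with a mean of -0.35 in RQ2617 and between -0.07 and 0.09 in the others. Genes of p53 and DNA damage were at -0.10 (adjusted p = 0.0604), with a mean of -0.36 in RQ2617 and between -0.02 and 0.02 in the others. Heat shock genes were at -0.07 (adjusted p = 0.0604), with means of -0.23 in RQ2617 and between -0.07 and -0.02 in the others, and ribosomal protein genes were at 0.03 (0.0604). The ribosomal list passed in 6 other settings, with a median of 0.09 without RQ2617 (adjusted p = 0.00708). Without RQ6897 the lists of G2 and mitosis (adjusted p = 0.0132), S phase (0.0132), p53 (0.0229), heat shock (0.0493) and chromatin silencing (0.02) passed, and without RQ7280 those of G2 and mitosis (0.0179), p53 (0.0179) and heat shock (0.0456). Heat shock genes also passed with another variance model (adjusted p = 0.0183), and G2 and mitosis genes with the mean of all probesets of a gene (0.0486). Chromatin silencing genes were at -0.10 (adjusted p = 0.0662), with a mean of -0.30 in RQ2617 and between -0.07 and 0.03 in the others. Erythroid genes were at -0.06 (adjusted p = 0.0732, and 0.0301 without RQ7387) and plasma cell genes at -0.08 (0.0851). Host factors of retroviral infection were at -0.09 (adjusted p = 0.136) and apoptosis genes at -0.09 (0.201), with means of -0.26 and -0.32 in RQ2617. Cell cycle inhibitors were at -0.03 (adjusted p = 0.246). Interferon response genes were at 0.03 (adjusted p = 0.396), monocyte genes at -0.07 (0.396), dendritic cell genes at -0.03 (0.332), immediate early genes at 0.01 (0.386) and glycolysis genes at -0.05 (0.396). Homing molecules were at -0.09 (adjusted p = 0.396), with a mean of -0.33 in RQ2617, stromal and endothelial genes at 0.06 (0.422), drug transporters at 0.01 (0.504) and respiratory chain genes at 0.01 (0.683, and 0.0462 without RQ2617). Antigen presentation genes had a median of -0.00125 and a mean of 0.05, and the test gave an upward direction (adjusted p = 0.296). The GFP+ array of RQ2617 had a narrower range of signals, with an SD of 2.15 against at least 2.25 on the other GFP+ arrays. Array weights were 0.419 for the arrays of RQ2617 and at least 0.993 for the others. Whether that narrower range lies behind the negative means of lists in RQ2617 was not tested.

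The calls of lists depend on the correlation assumed between genes, and all rest on 4 animals. With a correlation estimated per list, limma camera called 0 of 29 lists and gave 0 with an unadjusted p under 0.05, and limma fry called 0 with 2 under 0.05. In the 7 other ways of exchanging the fractions within animals, between 3 and 10 lists were called, against 7 in the real one.

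The 4 animals differed from each other in more probesets than the fractions did. Between animals 4155 of 40489 probesets passed the limma F test (10.3%), 2323 of them with 1 gene symbol. The named genes with the largest F statistics were OLFM4, S100A8, IL1A, ORM1, CCL20, S100A9, IFI44L, IL18RAP, CCL4L1 and IL6, with limma adjusted p between 2.11e-05 and 3.62e-05. S100A8 and S100A9, which encode the subunits of calprotectin, had signals of 11.69 and 11.44 in RQ2617 and of 11.83 and 11.45 in RQ6897, against 5.12 and 5.79 in RQ7387 and 7.09 and 6.46 in RQ7280 (log2, mean of both fractions). The inflammatory cytokine genes IL1A and IL6 were at 11.01 and 9.35 in RQ2617 and at 7.85 and 5.72 in RQ6897. In RQ7387 these 2 genes were at 4.65 and 3.73, and in RQ7280 at 5.17 and 4.20.

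Interferon response genes were highest in RQ2617, the animal sampled at 9 years. Of 32 measured genes 31 were highest in it and 30 passed the test between animals, and the median excess over the mean of the other animals was 1.67 (log2). The mean of the list was 9.14 in RQ2617 against 6.93 in RQ6897, 7.23 in RQ7387 and 7.48 in RQ7280. IFI44L was 4.58 above the mean of the other animals on the log2 scale (limma adjusted p = 3.17e-05), IFIT2 3.74 above (adjusted p = 0.000115) and ISG15, which encodes a ubiquitin-like protein, 3.42 above (adjusted p = 8.29e-05). TRIM22 was highest in RQ7387, at 10.62 against 10.26 in RQ2617. The GFP+ and GFP- means of the interferon list in RQ2617 were 9.12 and 9.16.

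**Figure D3:**
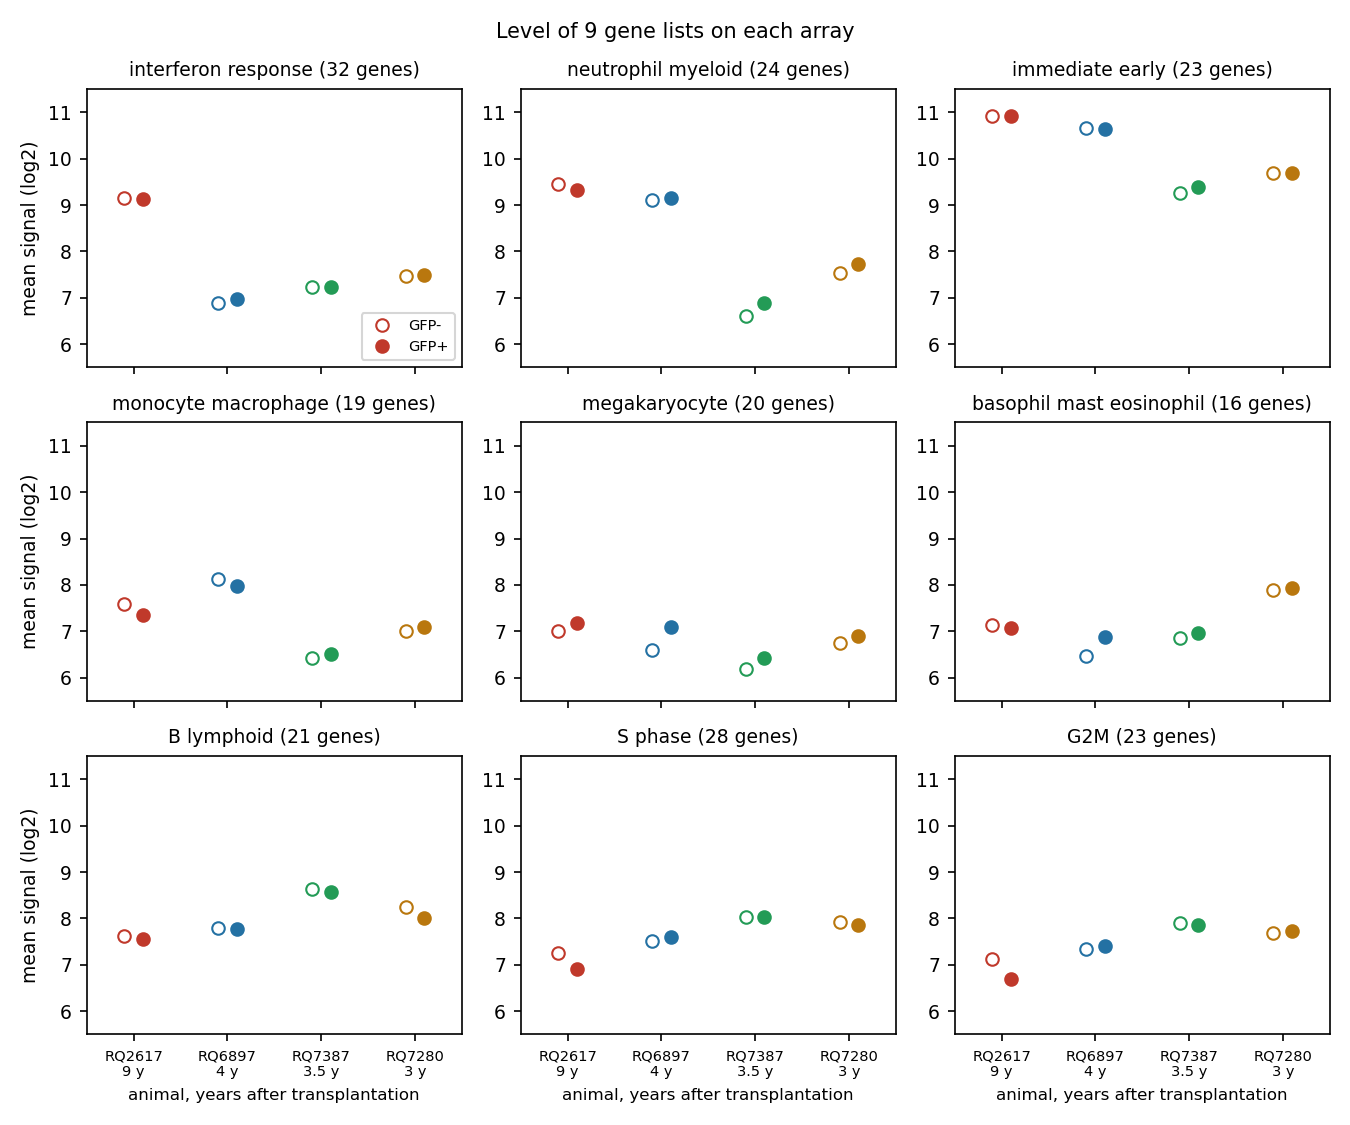
Mean log2 signal (vertical axis) of 9 gene lists on each of the 8 arrays, with the animals and their years after transplantation on the horizontal axis, open circles for GFP- and filled circles for GFP+. The interferon list lies at 9.12 and 9.16 in RQ2617, and its means in the other animals are 6.93, 7.23 and 7.48.

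Neutrophil and immediate early genes were highest in RQ2617 and RQ6897. The mean of the neutrophil list was 9.39 and 9.13 in these animals, 6.75 in RQ7387 and 7.63 in RQ7280, and 20 of its 24 genes passed between animals. Immediate early genes, which respond within minutes to stimulation or handling, were at 10.91 and 10.65 against 9.32 and 9.69, with 15 of 23 genes passing. Monocyte and macrophage genes were highest in RQ6897, where their median was 1.29 above the other animals, and 12 of 19 passed. B-lineage genes were highest in RQ7387, with a median excess of 0.90 and 14 of 21 genes highest in it. Of the whole list 15 genes passed, among them FCRLA, which was highest in RQ6897. BLK was at 9.62 in RQ7387 against 6.70 in RQ2617, and VPREB1, a part of the pre-B cell receptor, at 9.57 against 7.28. S phase and G2 and mitosis genes were lowest in RQ2617, where 23 of 28 and 21 of 23 genes had their lowest value (mean of both fractions). The GFP+ and GFP- means of RQ2617 were 6.90 and 7.25 for S phase, and 6.69 and 7.13 for G2 and mitosis. On the GFP- arrays of the other animals the lowest means were 7.51 and 7.35. Both lists were thus lowest in RQ2617 in each fraction, but by less in GFP- cells. Of the whole lists 17 and 11 genes passed, among them TYMS and CENPF, which were lowest in RQ6897. Basophil, mast cell and eosinophil genes were highest in RQ7280, with a median excess of 0.89 and 11 of 16 genes highest in it. Of the whole list 10 genes passed, among them EPX and PRG2, which were highest in RQ2617. MS4A2 was at 10.68 in RQ7280 and between 8.11 and 8.54 in the other animals.

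The arrays of an animal resembled each other more than those of different animals on average. The mean Pearson correlation of the GFP+ and GFP- array of an animal was 0.985, against 0.966 for arrays of different animals (exact one-sided permutation test over 24 pairings, p = 0.0417, the smallest the design allows). The correlation within RQ2617 was 0.972, the lowest within an animal. It lay above those of its GFP+ array with any other animal (at most 0.965) but below those of its GFP- array with the arrays of RQ6897 (0.978 and 0.979), and 2173 of its probesets differed by over 2-fold between the fractions, against 466 to 897 in the other animals. The correlations are across probesets, which are not independent replicates. Animal accounted for 71.2% of the sum of squares over all probesets with 3 degrees of freedom, the fraction for 8.48% with 1 and the residual for 20.3% with 3. The count between animals fell to 1070 without RQ7387 and to 2083 without RQ6897. Each animal was represented by 1 marrow sample at 1 time, so the animal could not be separated from the time or from the sampling and handling of that sample. The F test sets differences between these samples against the spread between fractions of a sample.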

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

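The tests for a single distant array were applied to 124 groups of 4 arrays, of which 4 were past the 95% limit of Dixon's test, while chance alone singles out about 1 in 20 groups, or 6.2. The values below were singled out by that test alone, with no explanation tested for them.

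All 4 concern animal RQ2617. The SD of the log2 signals of its GFP+ array was 2.15, the lowest of the GFP+ arrays, with the next at 2.25. Glycolysis genes had a mean of 10.36 on its GFP+ array, against at most 9.99 on the other GFP+ arrays. PINK1 was at 6.40 on its GFP- array, against at least 6.91 on the other GFP- arrays. The unnamed probeset 13813390 was at 10.17 on its GFP+ array, against at least 11.58 on the other GFP+ arrays.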

How the results depend on the processing

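Detrending on the signal level and counting identical probesets once were chosen after the data were seen. Without the replicate block 4 probesets and 2 lists passed between the fractions, and 36066 probesets had an interval within 2-fold. The paired and the unpaired fit thus differ in 3 probesets and 5 lists and in no call of a named gene. With unmoderated paired statistics, or with only singly named probesets, 0 probesets passed. All other settings gave 5 to 7 probesets, and leaving out 1 animal 2 to 6. For lists, camera with an estimated correlation and fry gave 0, leaving out 1 animal gave 5 to 9 and all other settings 7 to 9. The count between animals ranged from 1070 to 4030 when 1 animal was left out, which also leaves fewer arrays. How far that lowers the count was not tested. It was 4009 with quantile normalization. With only probesets at or above the median signal it was 5700, or 28.15% of those tested. Of 134 named genes 0 passed in any setting and 7 changed sign in at least 1. H1-1 was at 0.0175 with quantile normalization, 0.125 with array weights and 0.0257 detrended, and MZB1 at -0.0378 with array weights. Antigen presentation genes were at 0.0345 with quantile normalization, 0.0295 with array weights and 0.0434 detrended, and dendritic cell genes at 0.0003125 and 0.0161 with quantile normalization and detrended. With 1 animal left out the ranges were -0.15 to 0.0233 for PSMB9, -0.10 to 0.12 for MZB1, -0.15 to 0.23 for H1-1, -0.0867 to 0.44 for CD160, -0.07 to 0.19 for ERG, -0.0367 to 0.0667 for ATF4 and -0.18 to 0.06 for ITGA2B. For lists they were -0.03 to 0.0383 for antigen presentation, -0.14 to 0.04 for G2 and mitosis, -0.11 to 0.0133 for homing, -0.12 to 0.0267 for monocytes, -0.13 to 0.00667 for retroviral factors, -0.02 to 0.05 for insertion site genes, -0.0433 to 0.0767 for the respiratory chain, -0.0167 to 0.04 for immediate early genes and -0.0117 to 0.025 for drug transporters. For all changes of sign the cause was not tested. Of 435 comparisons of lists 362 kept their direction and side of the threshold, and so did 1586 of 1597 of genes. How far a signal lies above background limits all values and is not known for any probeset.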

Other observations

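Of the tests below, the one of platelet transcripts and the counts of splits for lists and for intervals were set before their results were seen. The tests of scaling, of single animals, of vector RNA, of the narrower array, of T cell dilution, of dendritic cells and of time, and the counts of splits for probesets, were chosen only after the result was seen.

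Other gene groups also stood apart in single animals. Stem cell and primitive progenitor genes had a median 0.34 above the other animals in RQ7280 and 0.33 in RQ7387, and -0.42 in RQ6897, with 14 of 25 genes passing the limma F test between animals. Megakaryocyte genes had a median excess of 0.34 in RQ2617 and of -0.57 in RQ7387, where 14 of 20 genes had their lowest value. Erythroid genes were 0.31 above the other animals in RQ7280 and at -0.41 in RQ7387. Glycolysis genes were 0.34 above in RQ2617, with 16 of 20 genes highest in it. Chromatin silencing genes were 0.45 above in RQ7387, with 19 of 27 genes highest in it. Ribosomal protein genes lay within 0.12 of the other animals in each animal, and 1 of 28 passed.

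Within the 68 consecutive unnamed probesets that hold the 6 called higher in GFP+ cells, 53 of the 62 others had a positive difference, and 11 had an unadjusted p under 0.05. Many of them share all values. Counting each set of values once, 42 of 50 were positive and 4 had an unadjusted p under 0.05. Of these, 13813358, 1 of 8 among the 11 with the same values, had 7.22 ± 1.39 in GFP+ and 6.07 ± 1.28 in GFP- cells (log2, mean ± SD, n = 4), a difference of 1.15 in 4 of 4 animals that did not pass the adjusted test. It was named after its value was seen.

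The 6 unnamed probesets were higher in GFP+ cells in every animal. Scaling of the arrays would shrink them, but the smallest difference was 2.53 after quantile normalization. With array medians already close, that step could change little. The smallest difference within any animal was 2.22, so each animal shows it. The paired test that chose these probesets favours such a pattern, so this is no separate support. A candidate explanation is RNA of the vector, by which the fractions were sorted. All 6 lie within 68 consecutive probesets, but the lack of a symbol there is no evidence for it, since 0 of the 11120 probesets after the last named one have one. Sequences of the probes were not used here, which keeps this open, and macaque transcripts without a symbol remain possible.

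The megakaryocyte list was higher in GFP+ cells in 4 of 4 animals. The narrower range of the GFP+ array of RQ2617 is argued against as the whole cause, since without that animal the median was 0.24 (limma camera adjusted p = 7.54e-08). A loss of T and natural killer cells alone among GFP+ cells would raise all other types alike. The B-lineage list was instead at -0.0875, with means from -0.25 to -0.03 per animal, although its own call was lost in several settings. A lower share of T, natural killer and B-lineage cells together would lower both lists, was not tested and stays open. Platelet RNA, which a CD34 sort may not remove from cells with attached platelets, would also bring transcripts outside the list. Of these, 24 had a median of 0.00625 (95% bootstrap interval over transcripts -0.08 to 0.07), and the 9 with low signals had -0.08 (-0.15 to 0.07). CAVIN2 was at 0.47 and NRGN at 0.26, and TAGLN2 and THBS1, at signals of 11.68 and 11.47, could hide a small share. PF4V1 (1.05) and RGS18 (0.81), in neither the list nor the 24 and singled out for their differences, were higher in 4 of 4 animals. The choice of transcripts thus decides the outcome, and platelet RNA stays open. A further open hypothesis is a larger share of megakaryocyte-biased progenitors among marked cells, which bulk arrays cannot separate from higher expression per cell. The call of the list itself was lost with an estimated correlation (limma camera adjusted p = 0.683).

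The interferon list was higher in RQ2617 than in the other animals in both fractions. Scaling of the arrays is argued against, since the median excess was 1.74 after quantile normalization, although array medians were already close before it. A larger share of dendritic cells, a source of interferon and of its response genes, would raise their markers, but the median of the dendritic list was at -0.22. Of its 12 measured genes 3 were highest and 5 lowest in RQ2617. Only 12 of 18 listed genes were measured, and IL3RA, CLEC4C and LILRA4 were not among them. The list thus cannot decide on a larger share of 1 kind of dendritic cell. The longer time after transplantation may play a part and cannot be told apart from the animal, because 1 animal was sampled at that time. Infection or inflammation in that animal, and the handling of its 1 marrow sample, are untested.

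Other splits of the 8 arrays were counted for each model. Of the 8 splits that keep 1 array of each animal on each side, the real one included, 1 gave as many probesets as the real one (7, highest other 0), 2 gave as many lists (7, highest other 10) and 3 left as few intervals within 2-fold (39002, lowest other 38921). With 8 splits no share under 0.05 can be reached. Without the pairing, 3 of 35 splits gave at least the 4 probesets of the real one, and the highest other gave 1859. Both others set whole animals against each other, RQ2617 and RQ6897 against RQ7387 and RQ7280 (1859) or RQ2617 and RQ7387 against RQ6897 and RQ7280 (57), which points to the structure by animal. The 7 other splits that part all 4 pairs, like the real one, gave 0 in that fit. For the megakaryocyte and the stem cell list the smallest adjusted p in the 7 other paired splits was 0.0016 and 0.00022, against 2.07e-06 and 6.15e-05 in the real one.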
